A study of Homo sapiens with 14 samples.

How the data were processed

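The counts used were those deposited by the authors, 1 file of HTSeq gene counts per library, and no read was realigned. The submitters' processing notes name FastQC 0.11.9, STAR 2.7.8a with GRCh38.p13, SAMtools and HTSeq 2.0.3. Total RNA was taken with Trizol per the labels. The annotation release, the strand setting and the read layout are not given in the sources used here. Each file held 62757 genes and 5 summary lines. A symbol was found for 62639 genes, and 58318 stood in GENCODE 29, which gave coordinates and gene types. Reads on no gene made up 48.7% to 50.0% of all reads, ambiguous reads 2.09% to 2.48%, and reads with more than 1 alignment 2.36% to 3.22% in libraries without a hairpin and 4.64% to 4.99% in libraries with one. Mitochondrial messenger RNA was 0.726% to 0.947% of assigned counts with a hairpin and 2.31% to 3.51% without.

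Genes were tested with edgeR's quasi-likelihood F-test, TMM normalization, the filterByExpr filter at a minimum count of 10 and Benjamini-Hochberg adjustment at 0.05, with 1 mean per group. The 8 parental and DDP libraries formed 1 fit with 23031 genes tested, and the 6 hairpin libraries another with 19044. A fit of all 14 libraries, with 24193 genes, served the comparison of shNC with the libraries labelled OVCAR3-DDP. Residual degrees of freedom were 4, 3 and 7 in that order, and the biological coefficient of variation 0.104, 0.106 and 0.106. Difference between lines was an interaction contrast. The 40 gene lists, 32 of biology, 3 of other cells and 5 of library quality, were tested with camera at a preset correlation of 0.01, again with the correlation estimated, and with fry. Replicates were compared on genes with a pooled count of at least 20, and their chi-square per gene ran from 3.88 to 31.5, so no replicate duplicated another.

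The comparisons, the tests, the gene lists and the rule for naming genes were written before the data were examined. The rule named ADAR, ADARB1 and ADARB2. It added the 8 risen and 8 fallen protein-coding genes with the largest fold change that passed, reached 10 CPM in the higher group and had replicates that did not overlap. With the hairpins all 4 libraries had to lie on one side and both hairpins had to be called with the same sign. It also named 4 members of each biology list that passed and up to 2 of the others, 5 genes each way for the line difference and 6 for each class of overlap. The text prints a part of the genes so named. Alternatives tried were DESeq2 size factors, upper-quartile scaling, no low-count filter, a mean of at least 5 CPM, a fold change of at least 2, DESeq2's Wald test, limma-voom, fits of all 14 libraries or of the compared groups alone, a replicate block and leaving out each library. A group at 0 counts was set to a floor of 3 counts over the group to bound a fold change. With 1 to 3 counts, a 95% counting interval was used.

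A self-test simulated counts from the averaged levels of each line and 1 fitted spread per gene over all groups. It changed 200 genes at 5 CPM or more and ran the same tests. Changes in genes below that level and groups of unequal spread were therefore not tested. At a 2-fold change, calls were made in 98.5% of the changed genes for OVCAR3, 92.5% for A2780, 82.1% for the line difference, 100% for the mean of the hairpins, and 97.0% for sh1 and for sh2. At 1.5-fold the line difference recovered 17.9%, A2780 56.7%, sh1 53.7% and sh2 52.2%. Unchanged genes called numbered 7 to 25. A planted list passed in all 7 comparisons, and 0 of 20 random lists did. The simulated genes varied independently, so this could not test the preset correlation of 0.01 on which the list calls rest. Software was R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.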

Results

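RNA was sequenced from cells labelled OVCAR3 and A2780, human ovarian cancer cell lines, in 14 libraries that fall into 7 groups of 2. Each line had a parental group and a group labelled DDP, an abbreviation of cisplatin, for its platinum-resistant derivative. The other groups were labelled OVCAR3-DDP with a short hairpin RNA: shNC, used here as the hairpin control, and sh1 and sh2, which target ADAR1. ADAR1, encoded by ADAR, converts adenosine to inosine in double-stranded RNA. Editing levels cannot be read from gene counts and were not analysed here. Counts assigned to genes ran from 20428538 to 49115255 per library. Parental OVCAR3 had 35864655 and 49115255, the libraries labelled OVCAR3-DDP 34544898 and 34455993, parental A2780 31195174 and 32711137, and A2780-DDP 34506558 and 32804363. The shNC libraries had 23697078 and 22987515, sh1 23746370 and 21244015, and sh2 20428538 and 23628936. Levels are given as CPM, counts scaled to the total assigned to genes in each library, as mean ± SD with n = 2 per group. Fold changes are given as log2 with an approximate standard error (SE). Where a group held few counts, the SE can be smaller than counting error alone and then understates the uncertainty. This holds for CA9 and KRT7 in OVCAR3 and for MGST1 and ABCC2 in A2780, among others. Nothing in the labels says that the replicates were separate cultures, so p-values measure only the spread between these samples, technical or biological. Intervals and floors cover counting error only.

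ADAR (ENSG00000160710.18; GRCh38, GENCODE 29, chromosome 1, 154582057 to 154628013, minus strand, protein coding) tested whether the targeted enzyme moved with resistance and with the hairpins. Its level was 502 ± 79.8 CPM in parental OVCAR3 (446 and 559) and 343 ± 10.1 CPM in the libraries labelled OVCAR3-DDP (349.7 and 335.5). ADAR was therefore lower in the libraries labelled OVCAR3-DDP, by log2 −0.73 (SE 0.12; edgeR adjusted p = 0.000113), in both libraries. In A2780 it was 566 ± 22.5 CPM in parental cells (582 and 549.9) and 572 ± 94.5 CPM in A2780-DDP (505 and 638), a log2 difference of 0.02 (SE 0.12; edgeR adjusted p = 0.924). Under the hairpins ADAR fell from 423 ± 34.1 CPM in shNC (447 and 399) to 272 ± 24.5 CPM with sh1 (289 and 254). It fell further to 115 ± 0.989 CPM with sh2 (116 and 114). The log2 changes were −0.71 (SE 0.11; edgeR adjusted p = 0.00123) for sh1 and −1.99 (SE 0.11; edgeR adjusted p = 2.07e-09) for sh2. Their mean was −1.35 (SE 0.09; edgeR adjusted p = 5.04e-08), and sh2 lay below sh1 by log2 −1.27 (SE 0.11; edgeR adjusted p = 5.86e-06). The second editing enzyme, ADARB1 (ENSG00000197381.18; GRCh38, chromosome 21, 45073853 to 45226560, plus strand, protein coding), fell from 121 ± 19.2 CPM in parental OVCAR3 to 27.2 ± 0.811 CPM in the libraries labelled OVCAR3-DDP (log2 −2.34, SE 0.13; edgeR adjusted p = 2.19e-09). In A2780 it stood at 16.9 ± 0.434 CPM in parental and 21.0 ± 3.04 CPM in DDP cells (log2 0.32, SE 0.13; edgeR adjusted p = 0.0675). That adjusted p became 0.0225 without A2780_DDP replicate 1 and ran from 0.0225 to 0.390 over the alternatives. ADARB1 did not pass with the hairpins (log2 −0.25, SE 0.10; edgeR adjusted p = 0.113). There it became 0.000956 and 0.0462 without OVCAR3_DDP_sh1 replicates 1 and 2, and ran up to 0.573 over the alternatives.

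**Figure D1:**
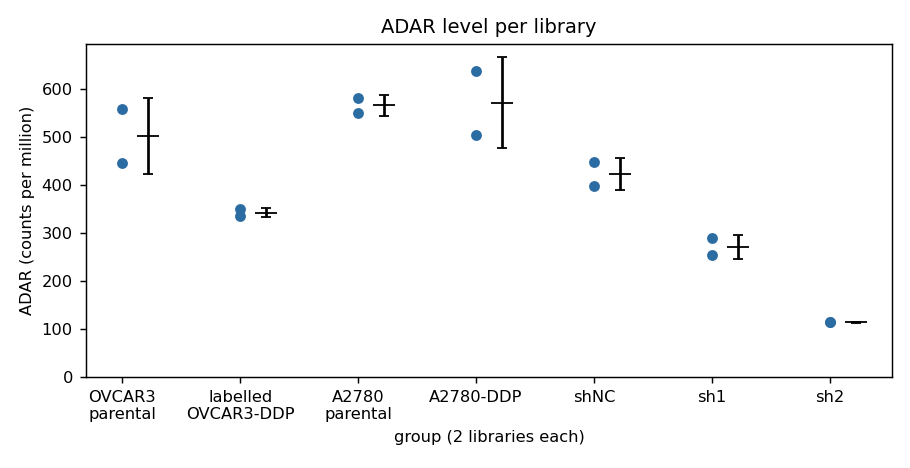
ADAR level in CPM (vertical axis) for each library (points), with the mean and SD of each group of 2 (lines and bars). The sh2 libraries sit at 116 and 114 CPM, below every other library, and A2780-DDP spans parental A2780.

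Whether the groups resembled each other as their labels imply was measured first on genes that mark cell identity. The keratin KRT7 was at 1083 CPM in parental OVCAR3, 0.246 CPM in the libraries labelled OVCAR3-DDP and 1006 CPM in shNC. The folate receptor FOLR1 was at 431, 0.304 and 1224 CPM in the same order, and mesothelin (MSLN) at 249, 0.464 and 349 CPM. The adhesion receptor CD44 stood at 564 CPM in parental OVCAR3, 0 counts in the libraries labelled OVCAR3-DDP and 888 CPM in shNC. Among 21700 genes, 256 were on (30 CPM or more) in parental OVCAR3 or the libraries labelled OVCAR3-DDP and off (under 0.3 CPM) in the other of the pair. The A2780 pair had 11 such genes, while parental A2780 against parental OVCAR3 had 272. The shNC, sh1 and sh2 groups had 8, 8 and 9 against parental OVCAR3, and 175, 177 and 181 against the libraries labelled OVCAR3-DDP. Against the libraries labelled OVCAR3-DDP, parental A2780 had 168 and A2780-DDP 146. The parental libraries themselves held little of some genes usual in ovarian carcinoma, with E-cadherin (CDH1) at 0.197 CPM and PAX8 at 4.08 CPM. The mucin MUC16 and the adhesion molecule EPCAM were low there too, and the transcription factor WT1 had 0 counts. The identity of the parental libraries therefore rests on the label as well. Pearson's r of log2 CPM across these genes, which are not replicates, was 0.830 for parental OVCAR3 against the libraries labelled OVCAR3-DDP and 0.964 within A2780. The on and off levels were chosen after seeing the data. Of the 256 genes, 3 in shNC, 5 in sh1 and 5 in sh2 lay nearer to the libraries labelled OVCAR3-DDP than to parental OVCAR3. Every direction given for OVCAR3-DDP in this section therefore describes only the untransduced libraries with that label.

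**Figure D2:**
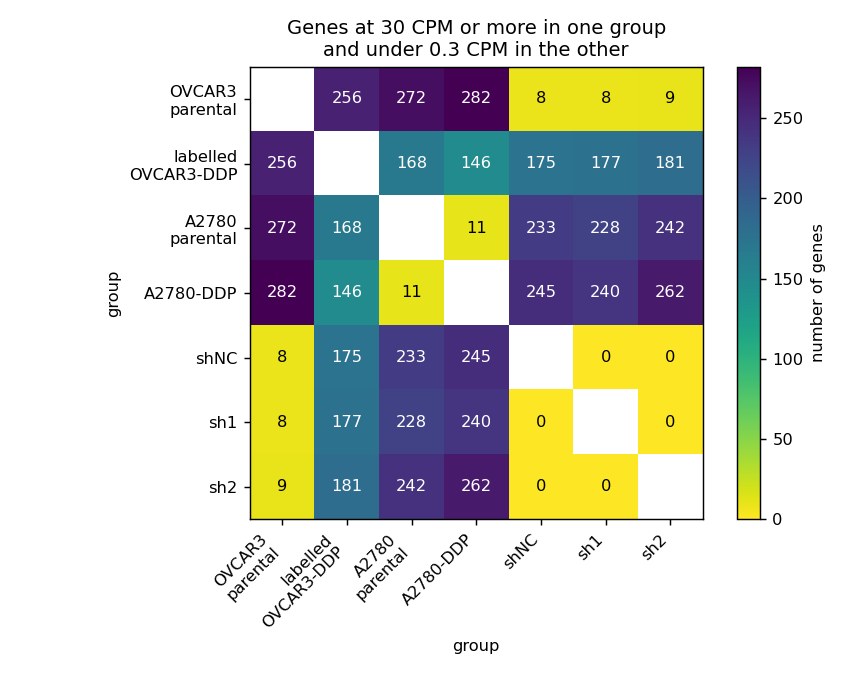
Number of genes at 30 CPM or more in one group and under 0.3 CPM in the other, written in each cell and shown by colour, for each pair of the 7 groups. The libraries labelled OVCAR3-DDP differ from parental OVCAR3 at 256 genes, near the 272 between parental A2780 and parental OVCAR3.

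The OVCAR3 comparison asked what differs between the libraries labelled OVCAR3-DDP and the parental line. The axonal motor KIF1A rose to 214 ± 2.28 CPM, the homeobox gene EN2 181 ± 3.36 CPM and the transcription factor MAF 144 ± 8.10 CPM. None had a count in parental OVCAR3, which makes them at least 6060-fold, 5122-fold and 4086-fold higher against a floor of 3 counts over the group. The Notch ligand DLL1 was at least 3432-fold higher and the hedgehog receptor SMO at least 3062-fold higher on the same basis. TM4SF1, a tetraspanin-like membrane protein that fell to 0 counts, was at least 15217-fold lower, CD44 at least 12935-fold lower and the growth factor binding protein IGFBP3 at least 3517-fold lower, both also at 0 counts. The chemokine CCL5 rose by log2 5.45 (SE 0.12) while the antiviral tetherin BST2 fell by log2 −4.51 (SE 0.12). The lactate exporter SLC16A3 fell by log2 −6.14 (SE 0.11; edgeR adjusted p = 3.73e-13), from 452 ± 18.6 to 7.25 CPM, in both libraries. Of 23031 genes tested with edgeR, 15784 passed at adjusted p < 0.05, 7685 higher and 8099 lower in the libraries labelled OVCAR3-DDP. The balance turned with the scaling, to 7959 higher and 7807 lower with DESeq2 size factors and 8450 and 7293 with upper-quartile scaling. At least 2-fold changes numbered 10055 of these, 5104 higher and 4951 lower. Without each library in turn the total ran from 13669 to 15301.

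HOX genes, which set position along the body axis, rose as a list in the libraries labelled OVCAR3-DDP, among them HOXD13 (log2 9.33, SE 0.22), HOXD10 (6.51, SE 0.22) and HOXB2 (5.71, SE 0.18). Of 36 tested, 32 rose and 1 fell, with the same numbers adjusted over the list alone (camera adjusted p = 5.99e-10, and adjusted p = 0.174 with an estimated correlation). Hypoxia and glycolysis genes fell, among them CA9 (log2 −10.38, SE 0.27), a carbonic anhydrase, and the pyruvate kinase PKM (−1.80, SE 0.09). In that list 22 of 29 fell and 4 rose, or 23 and 4 adjusted over the list alone (camera adjusted p = 1.86e-04, and adjusted p = 0.200 with an estimated correlation). Mitotic genes such as the kinetochore protein CENPF (−1.76, SE 0.10) and the kinesin KIF11 (−1.59, SE 0.09) fell, 18 of 25 with 1 risen by either adjustment (camera adjusted p = 0.00605, and adjusted p = 0.271 with an estimated correlation). Respiratory chain genes, with UQCRQ (−1.73, SE 0.12) and NDUFS3 (−1.38, SE 0.11), fell in 20 of 32 and rose in 0 by either adjustment (camera adjusted p = 0.0103, and adjusted p = 0.816 with an estimated correlation). Epithelial adhesion genes parted: KRT7 fell (−12.26, SE 0.25) and the tight junction protein OCLN rose (5.13, SE 0.15). There 16 of 26 fell and 6 rose by either adjustment (camera adjusted p = 0.0155, and adjusted p = 0.271 with an estimated correlation). Without OVCAR3_WT replicate 2 the camera adjusted p of epithelial adhesion became 0.0511, and over the camera alternatives it ran from 0.0141 to 0.271. Replication histones, a group that also tracks library preparation, fell in 17 of 20 and rose in 1 (camera adjusted p = 4.28e-04, and adjusted p = 0.271 with an estimated correlation). Interferon genes went both ways, 17 higher and 21 lower of 45, and did not pass as a list (camera adjusted p = 0.517).

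The A2780 comparison asked what the resistant derivative changed relative to its own parental line. The RNA-binding splicing regulator CELF2 reached 30.8 ± 1.29 CPM and the pluripotency factor SOX2 12.7 ± 1.41 CPM in A2780-DDP, both from 0 parental counts, at least 655-fold and 272-fold higher. The growth factor FGF20 rose from 2 counts, a ratio of 1248 (95% counting interval 345 to 10310.6). The lipoprotein receptor LRP1B rose by log2 9.70 (SE 0.23; edgeR adjusted p = 1.28e-11) and the heme-degrading enzyme HMOX1 by 3.72 (SE 0.10; edgeR adjusted p = 2.04e-11), the latter from 71.1 ± 0.956 to 931 ± 39.7 CPM, in both libraries. DCLK1, a microtubule-binding kinase, fell to 0 counts from 15.4 ± 1.85 CPM, at least 347-fold lower. The efflux pump ABCC2 fell by log2 −8.18 (SE 0.22), the efflux pump ABCB1 by −5.16 (SE 0.31) and the copper importer SLC31A1 by −1.52 (SE 0.10; edgeR adjusted p = 6.09e-08). SLC31A1 went from 233 ± 11.2 to 80.6 ± 6.18 CPM, lower in both libraries. Of the 23031 genes tested with edgeR, 8123 passed, 4145 higher and 3978 lower in A2780-DDP. Changes of at least 2-fold numbered 3507, 1793 higher and 1714 lower. Without each library in turn the total ran from 5432 to 7186.

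Interferon-stimulated genes fell in A2780-DDP, with the guanylate-binding proteins GBP2 (log2 −7.71, SE 0.23) and GBP1 (−2.65, SE 0.12), the antiviral SAMD9 (−4.72, SE 0.23) and the RNA-sensing enzymes OAS1 (−2.54, SE 0.15) and OAS2 (−2.99, SE 0.18). Of 45 tested, 27 fell and 4 rose, or 28 and 4 adjusted over the list alone (camera adjusted p = 4.76e-08, and adjusted p = 0.0788 with an estimated correlation). Mitotic genes, with CENPE (−1.57, SE 0.14) and AURKA (−0.92, SE 0.09), fell in 19 of 25 and rose in 2, or 20 and 2 adjusted over the list alone (camera adjusted p = 4.76e-08, and adjusted p = 0.0788 with an estimated correlation). Genes of entry into DNA synthesis rose in 17 of 25 and fell in 0, or 18 and 2 adjusted over the list alone, among them cyclin E1 (CCNE1, from 11.8 ± 1.26 to 43.9 ± 0.226 CPM) and the helicase subunit MCM2 (0.73, SE 0.08) (camera adjusted p = 7.88e-05, and adjusted p = 0.380 with an estimated correlation). Stress-response genes of protein folding and amino acid supply fell in 17 of 27 and rose in 2 by either adjustment, with the mTOR inhibitor DDIT4 at −3.14 (SE 0.10) (camera adjusted p = 5.59e-05, and adjusted p = 0.391 with an estimated correlation). HOX genes fell in 20 of 36 and rose in 3, or 21 and 3 adjusted over the list alone, with HOXB6 at −2.27 (SE 0.12) and HOXA13 opposite at 6.06 (SE 0.33) (camera adjusted p = 1.76e-06, and adjusted p = 0.0788 with an estimated correlation). Wnt targets such as the transcription factor TCF7 (2.87, SE 0.23) rose in 9 of 15 and fell in 2 (camera adjusted p = 0.00271, and adjusted p = 0.380 with an estimated correlation). Inflammatory genes, with the apoptosis inhibitor BIRC3 (3.75, SE 0.12) and the adhesion molecule ICAM1 (4.60, SE 0.19), rose in 11 of 22 and fell in 4 (camera adjusted p = 0.0368, and adjusted p = 0.329 with an estimated correlation). Platinum transport genes fell in 8 of 22 and rose in 4, or 8 and 5 adjusted over the list alone (camera adjusted p = 0.0305, and adjusted p = 0.380 with an estimated correlation). Platinum transport and inflammatory genes both lost their call with a replicate block (camera adjusted p = 0.118 each). Without A2780_DDP replicate 1 the camera adjusted p became 0.0783 for platinum transport and 0.0778 for inflammatory genes, and for the latter it became 0.0626 without A2780_WT replicate 2. Over the camera alternatives these ran from 0.0281 to 0.380 and from 0.0210 to 0.329. Immediate early genes, sensitive to handling, rose in 16 of 20 (camera adjusted p = 2.34e-09, and adjusted p = 0.0788 with an estimated correlation). Replication histones rose in 11 of 20 and fell in 0, by either adjustment (camera adjusted p = 8.64e-05, and adjusted p = 0.187 with an estimated correlation). Mitochondrially encoded genes, a list of library quality, fell in 11 of 13 (camera adjusted p = 2.33e-04, and adjusted p = 0.380 with an estimated correlation). RNA quality or preparation cannot be told apart from resistance here, which limits the other list calls. In all, 14 of 40 lists passed camera, 9 of them without each library in turn, and 0 with an estimated correlation.

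The line comparison asked whether the resistance-labelled groups changed alike. SOX2 was higher in both: the libraries labelled OVCAR3-DDP held 757 counts against 3 in parental OVCAR3, a ratio of 311 (95% counting interval 106 to 1510). The calcium-binding protein S100A4 was lower in both, by log2 −8.14 (SE 0.17) in OVCAR3 and −7.07 (SE 0.22) in A2780. DDIT4 also fell in both, by −3.21 (SE 0.10) and −3.14 (SE 0.10), with a difference between lines of −0.07 (SE 0.13; edgeR adjusted p = 0.734). The detoxifying enzyme MGST1 went opposite ways, 6.02 (SE 0.27) in OVCAR3 and −7.75 (SE 0.39) in A2780, as did the muscle scaffold protein PDLIM3 with 6.29 (SE 0.23) and −6.95 (SE 0.25). The matrix protein THBS1 fell by −8.63 (SE 0.23) in OVCAR3 and rose by 5.67 (SE 0.24) in A2780. Of genes called in both lines, 3540 had the same sign and 2625 the opposite, so 57.4% shared a direction. Both higher numbered 1818 against 1383 expected of independent lists, both lower 1722 against 1399. Higher only in the libraries labelled OVCAR3-DDP with lower in A2780-DDP numbered 1227 against 1327, and the reverse 1398 against 1458. Pearson's r of the fold changes was 0.120 and Spearman's rho 0.104 across genes, which are not replicates. Directions for OVCAR3 here come from the libraries labelled OVCAR3-DDP.

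The knockdown comparison asked which genes responded to the ADAR1 hairpins, averaged over sh1 and sh2, with SDs over the 4 knockdown libraries. CTH, which makes cysteine, rose from 4.45 ± 0.450 to 20.7 ± 4.06 CPM (log2 2.12, SE 0.19; edgeR adjusted p = 2.00e-06), in 4 of 4 libraries. The glutathione-degrading enzyme CHAC1 rose by 2.03 (SE 0.24; edgeR adjusted p = 5.86e-05) and the asparagine synthetase ASNS by 1.43 (SE 0.16; edgeR adjusted p = 4.48e-05), each in 4 of 4 libraries. For the genes of largest change, the naming rule required all 4 libraries on one side and both hairpins called. Neither is therefore separate support for those genes. TXNIP, an inhibitor of glucose uptake and thioredoxin, rose from 232 ± 17.7 to 669.6 ± 162 CPM (1.42, SE 0.11), and its relative ARRDC4 by 1.14 (SE 0.13). The double-stranded RNA sensor IFIH1 rose from 35.1 ± 1.27 to 72.1 ± 6.85 CPM (0.95, SE 0.12; edgeR adjusted p = 9.39e-05) and the antiviral RSAD2 from 86.6 ± 1.56 to 165 ± 15.9 CPM (0.84, SE 0.10; edgeR adjusted p = 8.68e-05), both in 4 of 4 libraries. The chemokine CXCL8 rose by 1.25 (SE 0.15), and BIRC3 by 0.94 (SE 0.13). The prolyl isomerase FKBP9 fell from 219 ± 4.84 to 114 ± 9.72 CPM (−1.04, SE 0.09), the mucin MUC1 by −0.93 (SE 0.11) and the collagen COL5A1 by −0.70 (SE 0.09). Of 19044 genes tested with edgeR, 150 passed with a change of at least 2-fold, 112 higher and 38 lower. In all 2270 passed, 1131 higher and 1139 lower. Among all genes that passed, the small excess of lower ones widened to 991 higher and 1254 lower with upper-quartile scaling. With DESeq2's Wald test the numbers were 1162 higher and 1356 lower, and with a replicate block 1085 higher and 1018 lower. The count was 223 without OVCAR3_DDP_shNC replicate 1, 268 without OVCAR3_DDP_shNC replicate 2, 6271 without OVCAR3_DDP_sh1 replicate 1, 3587 without OVCAR3_DDP_sh1 replicate 2 and 630 without OVCAR3_DDP_sh2 replicate 1. A group left with 1 library was assumed to vary like the others. Genes named by rule in this comparison were called in 88 of 96 cases, and 34 were called without each library in turn, those named in this paragraph among them.

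Hypoxia and glycolysis genes fell with the hairpins, with NDRG1, a stress-regulated differentiation gene, going from 7079 ± 121 to 4950.5 ± 347 CPM (log2 −0.61, SE 0.08), CA9 at −0.64 (SE 0.09) and the glycolytic enzyme GPI at −0.54 (SE 0.08). Of 29 tested, 18 fell and 0 rose, or 23 and 0 adjusted over the list alone (camera adjusted p = 1.08e-15, and adjusted p = 0.194 with an estimated correlation). Extracellular matrix genes, with COL5A1, the laminin LAMC1 (−0.66, SE 0.09) and the proteoglycan HSPG2 (−0.78, SE 0.12), fell in 17 of 30 and rose in 2 by either adjustment (camera adjusted p = 2.59e-09, and adjusted p = 0.285 with an estimated correlation). LAMC1 fell more with sh1, at 613 CPM in shNC, 327 with sh1 and 523 with sh2. COL5A1 (2556, 2056 and 1368 CPM in that order) and HSPG2 (491, 365 and 254) fell more with sh2. Inflammatory genes rose in 10 of 22 and fell in 1, or 11 and 2 adjusted over the list alone (camera adjusted p = 9.72e-07, and adjusted p = 0.284 with an estimated correlation). Stress-response genes, among them CHAC1, ASNS and the transcription factor ATF3 (0.75, SE 0.10), rose in 12 of 27 and fell in 2, or 14 and 4 adjusted over the list alone (camera adjusted p = 2.44e-05, and adjusted p = 0.284 with an estimated correlation). Ovarian lineage genes, with FOLR1 (−0.72, SE 0.08) and MSLN (−0.56, SE 0.09), fell in 4 of 9 and rose in 1 by either adjustment (camera adjusted p = 1.76e-04, and adjusted p = 0.284 with an estimated correlation). Homologous recombination genes, with the helicase BRIP1 (0.89, SE 0.14), rose in 8 of 40, or 9 adjusted over the list alone, and fell in 0 (camera adjusted p = 0.00109, and adjusted p = 0.519 with an estimated correlation). Interferon genes rose in 11 of 40 and fell in 5, or 16 and 8 adjusted over the list alone (camera adjusted p = 0.00840, and adjusted p = 0.284 with an estimated correlation). Without OVCAR3_DDP_shNC replicate 1 the interferon value became 0.0505, and the transcription factor IRF1 (0.68) and the antiviral IFIT2 (0.61) also lost their edgeR call, at adjusted p = 0.0605 and 0.0545, the highest over their alternatives. The interferon value ran from 0.00390 to 0.284 over the camera alternatives. Ribosomal protein genes fell in 9 of 36, or 20 adjusted over the list alone (camera adjusted p = 7.42e-08, and adjusted p = 0.550 with an estimated correlation). Mitochondrially encoded genes, a list of library quality, fell in 6 of 13, or 8 adjusted over the list alone (camera adjusted p = 1.58e-05, and adjusted p = 0.284 with an estimated correlation). Their messenger RNA was 0.947% and 0.925% of assigned counts in shNC. It was 0.856% and 0.867% with sh1, and 0.777% and 0.726% with sh2. RNA quality or preparation cannot be told apart from the knockdown here, which limits the other list calls. Nuclear noncoding genes fell in 2 of 6, or 4 adjusted over the list alone (camera adjusted p = 0.00840, and adjusted p = 0.284 with an estimated correlation). Immediate early genes rose in 5 of 17 and fell in 1, or 5 and 3 adjusted over the list alone (camera adjusted p = 0.0336, and adjusted p = 0.284 with an estimated correlation). That call was lost without OVCAR3_DDP_shNC replicate 1 (0.102) and without OVCAR3_DDP_sh1 replicate 1 (0.0563). In all, 18 of 39 lists passed camera, 9 of them without each library in turn, and 0 with an estimated correlation. With fry, which tests a list against no change, 5 of the 18 lost their call, among them homologous recombination and ribosomal protein genes (fry adjusted p = 0.137 each).

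**Figure D3:**
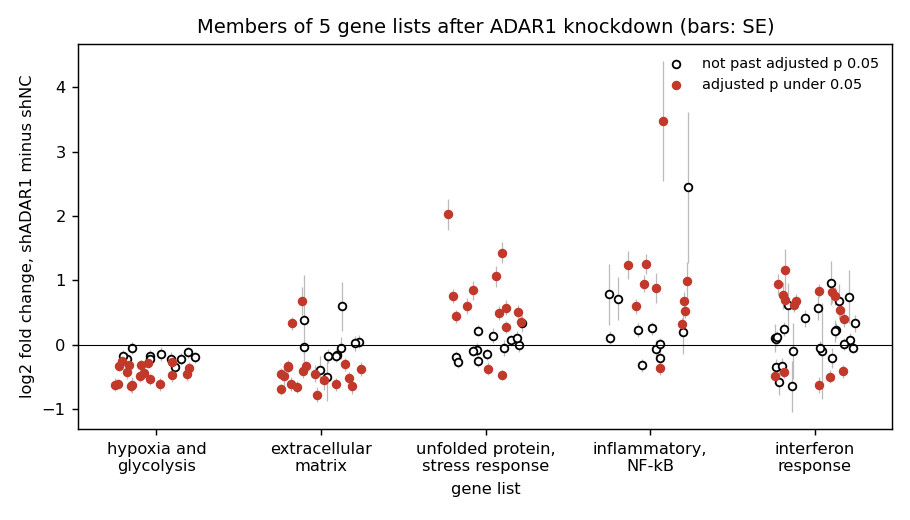
Log2 fold change (vertical axis) of each member of 5 gene lists with the ADAR1 hairpins against shNC, with bars for the SE and filled points for edgeR adjusted p under 0.05. Of 29 hypoxia and glycolysis genes 18 fell and 0 rose, and of 22 inflammatory genes 10 rose and 1 fell.

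The hairpins were also compared singly, to ask which genes moved with both. CTH rose by log2 2.09 (SE 0.21) with sh1 and 2.16 (SE 0.21) with sh2. TERT, the catalytic telomerase subunit, rose by 2.04 (SE 0.24) and 1.87 (SE 0.24), and the GTPase RND1 by 1.39 (SE 0.24) and 1.39 (SE 0.24). The secreted signalling protein CCN5 fell by −0.72 (SE 0.11) and −0.90 (SE 0.11), and FKBP9 by −0.93 (SE 0.11) and −1.15 (SE 0.11). INHBA, an activin subunit, was the 1 gene called in opposite directions, −0.63 (SE 0.13; edgeR adjusted p = 0.0118) with sh1 and 0.72 (SE 0.13; edgeR adjusted p = 0.00174) with sh2, and was named after its values were seen. With edgeR, sh1 called 725 genes (373 higher, 352 lower), sh2 called 2717 (1376 higher, 1341 lower) and sh2 against sh1 called 365 (127 higher, 238 lower). Fits of only the groups compared gave 445, 5874 and 192 in that order. These counts therefore depend on which groups share the estimate of spread. The balance of sh1 and sh2 turned with the scaling or the test, to 316 higher and 370 lower for sh1 and 1195 and 1472 for sh2 with upper-quartile scaling, and to 422 and 580 for sh1 and 1383 and 1486 for sh2 with DESeq2's Wald test. Both hairpins called 419 genes in the same direction, 259 higher and 160 lower, against 27.0 and 24.8 expected of independent lists. They share the shNC libraries, so unchanged hairpin groups were simulated against shared controls 20 times. The simulated fold changes correlated at r = 0.495 (0.479 to 0.513) against an observed r of 0.610. The simulation called at most 1 gene for sh1 and 2 for sh2, so it gives no measure of how many of the 419 arose from the shared shNC libraries. The 419 became 46 without OVCAR3_DDP_shNC replicate 1, 43 without OVCAR3_DDP_shNC replicate 2, 1812 without OVCAR3_DDP_sh1 replicate 1 and 102 without OVCAR3_DDP_sh2 replicate 1. The sh1 count was 108 and 74 without OVCAR3_DDP_shNC replicates 1 and 2, and 4449 and 1549 without OVCAR3_DDP_sh1 replicates 1 and 2. The sh2 count was 573 and 613 without the same shNC libraries, and 221 and 1349 without OVCAR3_DDP_sh2 replicates 1 and 2. The sh2 against sh1 count was 740 and 4262 without OVCAR3_DDP_sh1 replicates 1 and 2, and 47 and 69 without OVCAR3_DDP_sh2 replicates 1 and 2.

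The last comparison asked whether genes that differ in the libraries labelled OVCAR3-DDP moved back when ADAR was lowered. CHAC1 was lower in the libraries labelled OVCAR3-DDP by log2 −3.07 (SE 0.11) and rose with the hairpins by 2.03. ASNS moved likewise, −1.45 and then 1.43, as did the inhibin subunit INHBE with −4.25 (SE 0.13) and 1.26 (SE 0.18). MEGF6, an EGF-repeat protein, was higher by 0.98 (SE 0.18) and fell by −0.99 (SE 0.13) with the hairpins. FKBP9 and MUC1 went the same way in both, −1.23 and −1.04 for the former and −3.57 and −0.93 for the latter. The 2 changes started from different levels. MEGF6 was at 14.5 CPM in parental OVCAR3, 32.3 in the libraries labelled OVCAR3-DDP, 111 in shNC, 66.8 with sh1 and 52.8 with sh2. CHAC1 was at 68.4, 9.20, 1.93, 9.61 and 7.39 CPM in the same order. Moving back therefore means an opposite sign, not a return to the parental level. Of the genes called in both comparisons, 941 moved back and 827 moved the same way. Lower then higher numbered 636 against 461 expected of independent lists, and lower in both 565 against 463. Higher then lower numbered 305 against 336 expected, and higher in both 262 against 335. Both classes lower in the libraries labelled OVCAR3-DDP were in excess and both higher classes short, whichever way the knockdown went. Independent lists are thus a poor reference, and the excess of 636 alone does not show moving back. Pearson's r across 18312 genes was 0.0165, and camera gave p = 0.581 for the higher and 0.483 for the lower OVCAR3 set in the knockdown. The 941 became 71 and 91 without OVCAR3_DDP_shNC replicates 1 and 2, 2667 and 1451 without OVCAR3_DDP_sh1 replicates 1 and 2, and 249 without OVCAR3_DDP_sh2 replicate 1. In the same order the 827 became 104, 117, 2123, 1347 and 258. The shNC libraries themselves differed from the libraries labelled OVCAR3-DDP at 16860 genes by edgeR (7961 higher, 8899 lower). Of 15739 OVCAR3 calls, 9279 (59.0%) kept their sign in shNC against parental OVCAR3, with a median ratio of fold changes of 0.139. Both changes share the parental libraries, which raises these values, and no value without change was computed for them.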

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

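The tests of cell identity in this part were chosen after the result was seen. The difference between the lines was planned and tested as an interaction with edgeR.

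The change from parental to DDP libraries differed between OVCAR3 and A2780 at 12391 genes. ADAR differed by log2 −0.75 (SE 0.17; edgeR adjusted p = 0.00193) and ADARB1 by −2.66 (edgeR adjusted p = 4.26e-08), since both fell in the libraries labelled OVCAR3-DDP. Genes whose change, not level, was higher in OVCAR3 than in A2780 included the lysophosphatidic acid receptors LPAR3 (22.51) and LPAR1 (18.78). Others were the ubiquitin ligase RNF128 (19.54), the cyclin CCND2 (17.60) and the neurofilament gene NEFL (17.11). Reads of an opposite-strand gene leave NEFL uncertain. Genes whose change was lower in OVCAR3 than in A2780 included the somatostatin receptor SSTR1 (−17.88), the Notch-related DNER (−18.08), S100A6 (−18.47), MCTP2 (−18.83) and CD44 (−19.86). These differences are fitted values against groups at or near 0 counts and bound nothing. In level, CD44 stood at 564 CPM in parental OVCAR3, 0.0160 in parental A2780 and 0.102 in A2780-DDP. DNER stood at 77.7, 0.0153 and 0.221 CPM in the same order. LPAR3 was at least 887-fold higher in the libraries labelled OVCAR3-DDP and at least 56.2-fold lower in A2780-DDP. CCND2 went from 0.0558 to 177 CPM in OVCAR3 and from 155 to 2.41 CPM in A2780. SSTR1 and MCTP2 lost their call without A2780_DDP replicate 2 (edgeR adjusted p = 0.999879, log2 −15.49 and −14.65), and over the alternatives their lowest adjusted p were 4.28e-10 and 3.63e-15.

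The pattern weighed was that the libraries labelled OVCAR3-DDP stood as far from parental OVCAR3 as A2780 did, with 256 genes on in one and off in the other, against 272 for parental A2780 and 11 within the A2780 pair. The tables argue against a stable resistant state shared with the transduced libraries, since 3 of the 256 genes (1.17%) lay nearer to the libraries labelled OVCAR3-DDP in shNC, but such a state stays open if the transduced libraries derive from parental-like cells through a label error, which was not tested. Cells of another line may be in the libraries labelled OVCAR3-DDP, and HEK293-type cells are a candidate, with 5 of 6 markers at 10 CPM or more there and under 1 CPM in parental OVCAR3 (IRS4 433 CPM, LIN28B 53.1 CPM). That list and its bound were written after several levels had been seen, it passed exactly at the bound, 4 of 6 remain without NEFL (16.4 CPM), whose counts are uncertain, and INA, at 0.131 CPM, goes against it; parental A2780 reached 10 CPM for 2 of the 6 and A2780-DDP for 1, and the labels state no sort. An exchange with the A2780 libraries was tested and its entry then removed, with 146 genes against the nearer A2780 group and 11 within A2780, which speaks against it, and whether the parental libraries are OVCAR3 was not tested.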

How the results depend on the processing

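The replacement of OVCAR3-DDP by shNC and the removal of genes of the libraries labelled OVCAR3-DDP were chosen after seeing the data. Values that answer a comparison were counted once for each alternative. Of these, 240 kept their direction and side of the threshold or stayed within 1.5 times, 49 moved and 1 reversed. The reversed value was ADAR in A2780, which passed in neither case, at log2 −0.15 without A2780_DDP replicate 2 (edgeR adjusted p = 0.402), with fewer samples. Named genes and lists were also counted once for each alternative, and of these pairs 4167 stayed, 203 lost and 19 gained a call. Counted once each, 231 of 295 named gene results were kept under every alternative run. With changes of at least 2-fold, a stricter threshold, the counts were 10055 (OVCAR3), 3507 (A2780), 150 (mean of the hairpins), 83 (sh1), 266 (sh2), 55 (sh2 against sh1), 33 (both hairpins), 1366 and 821 (both lines, same and opposite), 39 (moving back) and 35 (same way). With a mean of at least 5 CPM, fewer genes tested gave 10267 for OVCAR3 and 10343 for shNC against the libraries labelled OVCAR3-DDP. With only the groups compared, sh1 gave 445, sh2 5874 and sh2 against sh1 192. The joint fit shared 1 estimate of spread over the hairpin groups. The sh1 pair varied most, with chi-square per gene 21.1 against 5.01 for shNC and 4.87 for sh2. The sh2 count therefore depended on the sh1 libraries. For sh2 against sh1, no filter gave 690 and DESeq2's Wald test 642, and the cause of these was not tested. Leaving out each library, with fewer samples, gave 13669 to 15301 (OVCAR3), 5432 to 7186 (A2780), 10663 to 12474 (line difference), 223 to 6271 (mean of the hairpins), 74 to 4449 (sh1), 221 to 1349 (sh2; 573 and 613 without the shNC libraries), 47 to 4262 (sh2 against sh1), 43 to 1812 (both hairpins), 2482 to 3481 and 1773 to 2584 (both lines, same and opposite), 71 to 2667 (moving back) and 104 to 2123 (same way). The lone library left in a group was assumed to vary like the other groups. Of the 223 and 268 genes called without either shNC library, 217 and 263 were among the 2270. ADAR ranged from log2 −0.80 to −0.57 (OVCAR3), −0.15 to 0.21 (A2780), −1.41 to −1.28 (mean of the hairpins), −0.83 to −0.62 (sh1), −2.05 to −1.92 (sh2) and −1.37 to −1.16 (sh2 against sh1). With a replicate block the counts were 15097 (OVCAR3), 7333 (A2780) and 2103 (mean of the hairpins), and correlations of paired residuals ran from −0.360 to 0.068. The block took the camera call from 4 A2780 lists, platinum transport, inflammatory and cancer-testis genes (adjusted p = 0.118 each) and double-stranded RNA sensors (0.120). With shNC in the place of OVCAR3-DDP, OVCAR3 gave 12463, the line difference 9903, and both lines 2627 the same and 2015 opposite. Without 324 genes of the libraries labelled OVCAR3-DDP the mean of the hairpins gave 2270. Upper-quartile scaling moved the median of all genes by 0.13 in OVCAR3 and 0.11 in the line difference (log2). Leaving out libraries was not run for shNC against the libraries labelled OVCAR3-DDP.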

Other observations

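The tests of mixed RNA and of strand were chosen after the result was seen, and the test of reads carried over from every library before.

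Genes that moved in A2780-DDP and with the hairpins formed no comparison of the report. TXNIP fell in A2780-DDP by log2 −5.53 (SE 0.12), from 101 to 2.17 CPM, and rose with the hairpins by 1.42. CTH fell by −1.32 (SE 0.11) and rose by 2.12, and INHBE fell by −2.18 (SE 0.14) and rose by 1.26. TERT rose in both, by 1.79 (SE 0.16) and 1.95 (SE 0.22). Lower in A2780-DDP then higher with the hairpins numbered 344 genes against 210 expected of independent lists, and lower in both 271 against 211. Higher then lower numbered 251 against 215, and higher in both 212 against 214. Both classes lower in A2780-DDP were in excess, so independent lists are a poor reference here too. Leaving out libraries was not run for these 4 counts, and the knockdown calls behind them depend strongly on single libraries. Pearson's r across genes was −0.0473, and camera gave p = 0.675 for the higher and 0.189 for the lower A2780 set in the knockdown (0.393 and 0.0401 with an estimated correlation). Parental OVCAR3 also held little of the mucin MUC16 (3.68 CPM) and of the adhesion molecule EPCAM (16.4 CPM), and 0 counts of the transcription factor WT1, so every OVCAR3 comparison rests on the label of the parental libraries.

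The transduced libraries held a low level of genes that were on in the libraries labelled OVCAR3-DDP and off in parental OVCAR3, with a median share of 0.543% to 0.666% of their level there. Reads carried over from every library of the series would bring A2780 genes alike, and those reached a median share of at most 0.0344%, which argues against that source. RNA of cells like those labelled OVCAR3-DDP may have been mixed in, but 69.1% of the genes in the lowest library lay within 3-fold of the median share, where a simulated mix of 0.5% gave 94.6%. That simulated mix held counting error only, so its value is not a fair reference. The 69.1% lay between the bounds for and against mixing, which were set by hand after the result was seen. Mixing therefore stays open, and so do reads carried over from the libraries labelled OVCAR3-DDP alone. No biological explanation was tested.

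Antisense genes were counted beside their coding partners, with a median read density 1.40 times that of the partner over 188 pairs (quartiles 1.02 to 1.80), and at least 48.7% of reads in each library lay on no gene. Counting with strand in libraries that do not mark strand may explain both. No biological explanation was tested. Counts of genes with an opposite-strand neighbour, such as ENC1 and BCL2L1, are therefore uncertain.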
